A study of Homo sapiens with 12 samples.

How the data were processed

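RNA from 6 breast cancer cell lines, BT474, MCF-7, MB-231, MB-468, T47D and BT-549, was measured on 12 one-colour arrays, 2 per line. Per the labels' protocols, total RNA was taken with Trizol, cleaned with a mirVana kit, amplified linearly by the Eberwine method and labelled as cDNA with Cy3. Per the file headers, the arrays were read in 1 channel on an Agilent scanner and quantified with Agilent Feature Extraction, version 11.5.1.1, and the array design was drawn on the human assembly hg19. Per the file headers, the processed signal of each spot is an intensity on a linear scale, already background-subtracted and detrended within the array and not normalized between arrays. The flags for spots well above background, saturated or uneven are values of 0 or 1 and of no other kind, per the file headers. The deposited value table holds intensities as well, with no scale stated. Against the scanner files, each column equals the geometric mean of the processed signal over a probe's spots that carry no flag, for 100% of the probes with such a spot, within a log2 difference of 0.0001. Probes with every spot flagged on an array could not be compared, though the deposited table holds values for some of them. It is therefore linear, and nothing else about its scale or centring stays unknown. Its medians for replicate 1 were 24.8 in BT474, 25.2 in MCF-7, 21.1 in MB-231, 35.0 in MB-468, 26.1 in T47D and 18.2 in BT-549. For replicate 2 they were 51.6, 62.1, 43.5, 46.5, 38.9 and 36.4 in the same order.

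Each array holds 60901 spots of probes that are not controls, for 58201 probes. Between 59.3% and 69.7% of the spots were well above background, 0 were saturated, and 106 to 615 were flagged as uneven or outlying and left out. The 75th percentile of the processed signal had a median of 335 on slide 1 and 606 on slide 2. Each slide held 1 array of each line, and the slides were scanned on the same day. The slide differences of 2 lines correlated across probes in all 15 pairs of lines (0.14 to 0.45, median 0.33), so the replicate number marks the slide, which was used as a block in alternatives. For arrays, their number limits the precision.

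The main values were the log2 of the processed signal minus the array's 75th percentile over all probes that are not controls. Spots of a probe were averaged. Probes were tested if well above background on both arrays of at least 1 line. A gene was represented by the probe with the highest mean signal, and 5442 genes tested had more than 1 probe. The files hold accessions but no gene symbols, so names were taken from a RefSeq table on GRCh38.p14, which matched 24751 of 25277 probes of protein-coding transcripts and 6287 of 6493 of noncoding ones. None of 9747 probes with Ensembl transcript names could be named. In all 31104 probes were named, for 22439 symbols. Of 35524 genes and probes tested, 19319 had a symbol and 16205 stayed unnamed. Genomic positions are not given, since the design and the table rest on different assemblies.

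Fits were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (1.17.8) and jsonlite 2.0.0 for reading and matplotlib 3.10.9 for drawing. The response groups were compared on the 6 line means, 2 against 4, since the response belongs to the line. Separation of the groups was tested on the 12 arrays with the largest p of the 8 differences between a sensitive and a resistant line, where all 8 had the same sign. Each resistant line was compared with the mean of the sensitive lines, and BT474 with MCF-7, in the same fit, with a minimum absolute log2 fold of 1. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. Gene lists were tested with camera on the line means, with a preset correlation of 0.01 between genes and, as an alternative, one estimated for each list. CD47 and other single genes were also tested with an exact two-sided permutation test of the line means.

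There were 22 lists with 574 genes, of which 542 were tested. They cover inhibitory ligands of phagocytosis, pro-phagocytic signals, complement regulators, MHC class I, interferon-stimulated genes, myeloid cytokines, NF-kappaB targets, luminal, basal, mesenchymal, epithelial and ERBB2-region genes, proliferation, cholesterol synthesis, glycolysis, the unfolded protein response, sialylation, integrins, apoptosis, macrophage markers, fibroblast and endothelial markers, and stress genes. The lists, the comparisons, the tests, the rule for named genes and the alternatives were set before the data were examined, except where the text says otherwise. The rule named 14 genes in every case, CD47 among them, and for each comparison the genes with the largest difference among those past the threshold, up to 10 in each direction for the response groups, 3 for each resistant line and 5 for BT474 against MCF-7. For each list it named up to 4 members with the largest difference. Genes had to be well above background on the brighter side and to have a symbol, and sex-linked marker genes were left out.

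The steps were tested on simulated data with known changes. With the lines as replicates, a log2 change of 4 was found in 44.8% of 67 changed genes and one of 8 in 78.8% of 66, but one of 2 in 0%. In that run 5 genes or probes left unchanged were called as well. The test of separation found 61.2% at a gap of 2 and 97.0% at 4, and called 0 unchanged genes that did not separate in the real data. For single lines a log2 change of 2 was found in 56.7% to 71.6%, and 4 to 12 unchanged genes or probes were called. A list shifted by 1 was called in 18 of 20 draws and an unshifted list in 1 of 394, with genes simulated without correlation between them.

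Most alternatives replaced 1 choice, and some changed more than 1 together. Normexp background correction with an offset of 50 was joined to quantile normalization, and the line as a random block was also fitted together with the slide as a block. The alternatives were normexp with quantile normalization, quantile normalization of the processed signal, the array median, the percentile over probes detected on all arrays, the deposited table, no filter or a stricter filter on dim probes, the mean of a gene's probes, an intensity trend with a robust prior, a replicate or a line left out, single slides, the slide as a block, the line as a random block, the arrays as independent samples, other fold thresholds, and fits of the compared lines alone. The files hold no mean signal of a spot, so normexp used its median signal and median background, a further change from the processed signal. Control spots were left out of all comparisons.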

Results

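Gene expression was measured in 6 breast cancer cell lines that the series divides by their response to an antibody against CD47, the cell-surface protein that restrains phagocytosis by macrophages through its receptor SIRPA. BT474 and MCF-7 are the sensitive lines, and MB-231, MB-468, T47D and BT-549 are the resistant ones. BT474 is commonly described as ERBB2-amplified, MCF-7 and T47D as oestrogen-receptor-positive, and MB-231, MB-468 and BT-549 as lacking oestrogen receptor and ERBB2 amplification. Each line gave 2 biological replicates per the labels, 1 on each of 2 slides, so that 12 arrays were compared, 4 of sensitive and 8 of resistant lines. Between 59.3% and 69.7% of the spots of an array were well above background, and no spot was saturated. Replicates of a line correlated across probes at Pearson's r of 0.9748 to 0.9890, and arrays of different lines at 0.828 to 0.955; probes are not independent replicates. All levels are log2 signal relative to the array's 75th percentile. On the arrays labelled MCF-7, the oestrogen and progesterone receptor genes ESR1 (-2.51) and PGR (-2.23) were lower than in BT474 and T47D. Those arrays also carried genes of intestinal type, such as VIL1 at 3.96. Whether those samples hold MCF-7 cells alone is not settled, and every comparison that uses them as a sensitive line carries this doubt. The number of lines, 2 against 4, limits the precision of every comparison between the response groups. MB-231 and MB-468 count as 2 of the 4, though their line means correlated at 0.958, against 0.901 for the next pair. If their samples share RNA, which is not settled, the p-values between the groups count that source as 2 lines and are too small.

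The first question was whether the antibody's target is itself expressed differently. CD47 (probe A_23_P6935) was well above background on all 12 arrays. Its mean level was 3.13 in the sensitive lines, 3.36 in BT474 and 2.91 in MCF-7, and 2.71 ± 1.36 (SD, n = 4) in the resistant lines. The resistant lines fell on both sides of the sensitive ones: CD47 was 3.91 in BT-549 and 3.86 in T47D, but 1.65 in MB-231 and 1.41 in MB-468. Against the mean of the sensitive lines, CD47 fell by 1.48 ± 0.19 (SE) in MB-231 and by 1.73 ± 0.19 in MB-468, with limma adjusted p of 1.74e-04 and 8.17e-05. In T47D and BT-549 it was higher by 0.73 and 0.78, which passed on p (0.0153 and 0.0088) but not on the minimum log2 fold of 1. The SE and p of comparisons of single lines, here and below, measure only the spread between the 2 samples of a line. Sensitive minus resistant, the difference was 0.43 ± 0.89 (SE; 95% interval -1.74 to 2.59), with an exact two-sided permutation p of 0.733 over the 15 splits of the lines. That test cannot give a p below 0.0667, the smallest for 2 lines against 4. The difference was 0.43 on slide 1 and 0.42 on slide 2, and -0.01 without MB-468, whose arrays resemble those of MB-231 beyond any other pair.

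Among the other genes of the phagocytosis checkpoint, SIRPA was higher than in the sensitive lines by 2.86 in MB-468 and by 1.31 in T47D, and lower in MB-231 (-2.40) and BT-549 (-1.14), each past the threshold. CD24, another surface protein that restrains phagocytosis, was 4.14 in the sensitive lines and nearly equal in T47D (4.30) and BT-549 (4.26), but -0.04 in MB-231 and -0.01 in MB-468, where it passed as lower. QPCTL, the enzyme that modifies CD47 for SIRPA binding, was past the threshold in BT-549 alone of the resistant lines, higher by 1.29. LRP1, the receptor for calreticulin on phagocytes, was higher in MB-231, MB-468 and BT-549 by 3.30, 1.49 and 4.23, and its difference of 0.80 in T47D did not pass. CALR, calreticulin itself, was higher in BT-549 by 1.20 and in T47D by 1.01, and its differences in MB-231 (0.45) and MB-468 (0.55) did not pass. B2M, the light chain of MHC class I, passed in T47D (1.27 higher). SLAMF7, a receptor that takes part in phagocytosis, was not well above background on any sensitive array and was higher in MB-231 and MB-468 by fitted values of 4.08 and 2.52. With the lines as replicates none of these genes passed between the response groups (adjusted p from 0.749 for LRP1 to 0.987 for SIRPA), in a design that found 0% of simulated log2 changes of 2. LRP1 and CALR were lower in both sensitive lines than in every resistant line, with gaps of 0.0582 and 0.0393 that did not pass. For LRP1 this held only on its brightest probe, used here. On its other probe, also detected on all 12 arrays, T47D (-2.72) lay below MCF-7 (-2.62). Of the 15 measured genes of the fixed list of inhibitory ligands of phagocytosis, none passed over all genes with the lines as replicates and 1 adjusted over the list alone, CD200, a ligand that restrains myeloid cells. CD200 was also higher in both sensitive lines than in every resistant line, a separation that passed over all genes on the 12 arrays (adjusted p = 0.0440), and it passed with the line as a random block. CD200 was well above background on all 4 sensitive arrays (-2.59 in BT474, -2.23 in MCF-7) and on 2 of 8 resistant ones, so its fitted difference of 3.89 is inexact. The list as a whole did not pass (camera adjusted p = 0.521). Its median was -0.16 and its mean 0.35, so the sign depends on the summary, and the camera direction followed the median.

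**Figure D1:**
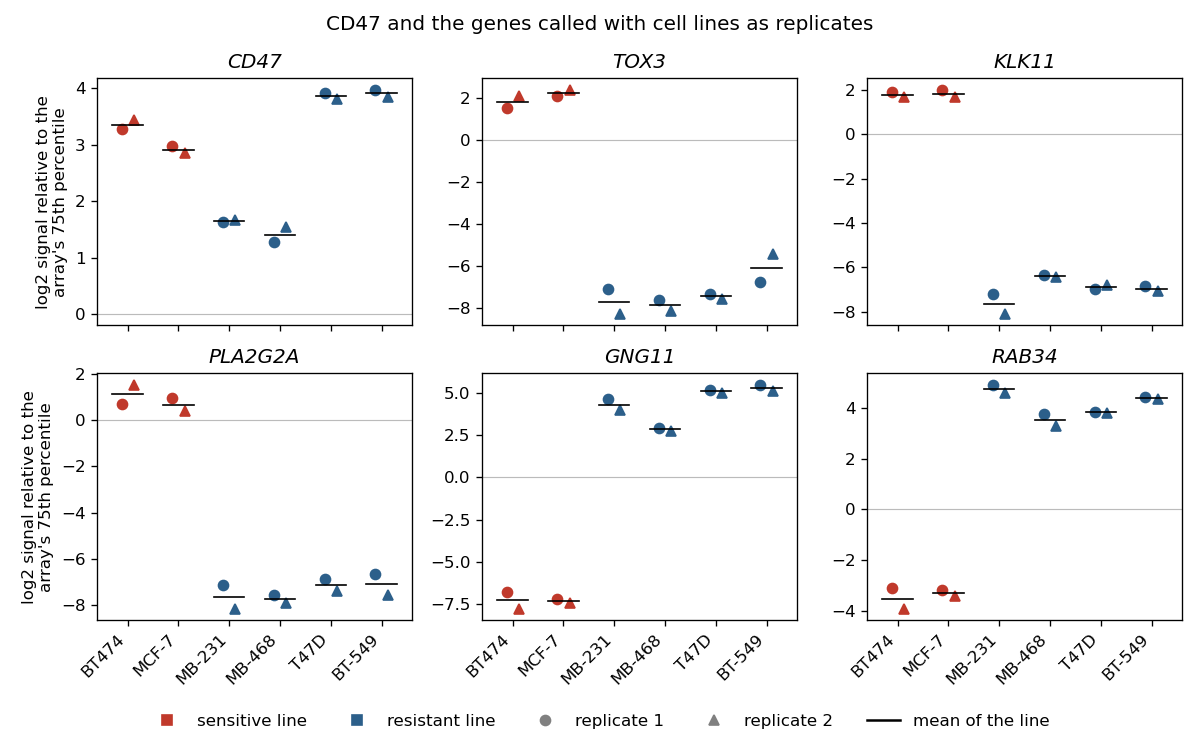
Log2 signal relative to the array's 75th percentile (vertical axis) of CD47 and of the 5 genes that passed with cell lines as replicates, by cell line (horizontal axis); circles are replicate 1, triangles replicate 2, and bars the mean of a line. CD47 in the sensitive lines (red) lies between the resistant lines (blue), whereas TOX3, KLK11, PLA2G2A, GNG11 and RAB34 leave a gap between the groups.

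The main comparison asked which genes differ between sensitive and resistant lines when each line counts once. TOX3, a chromatin-associated protein of luminal breast cells, was at least 170-fold higher in the sensitive lines (2.05 against -7.26, difference 9.31 ± 0.58 SE, limma adjusted p = 0.0268). KLK11, a secreted serine protease of the kallikrein family, was at least 145-fold higher (1.82 against -6.97, adjusted p = 0.0133), and PLA2G2A, a secreted phospholipase, at least 75.5-fold higher (0.88 against -7.40, adjusted p = 0.0133). GNG11, a G protein gamma subunit, was at least 844-fold lower in the sensitive lines (-7.31 against 4.41, adjusted p = 0.0268). RAB34, a small GTPase of membrane traffic, was well above background in all lines and lower in the sensitive ones by a log2 difference of -7.55 ± 0.44 (SE; adjusted p = 0.0268). TOX3, KLK11 and PLA2G2A were not well above background on any resistant array, nor GNG11 on any sensitive array. The fitted differences of these genes are therefore inexact, and their SE and p rest in part on the spread of background signal. The "at least" folds set the brighter group's mean against, on each array of the dimmer group, the higher of the probe's own signal and the lowest signal of any probe well above background.

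These 5 genes, 3 higher (60%) and 2 lower, were all that passed among 35524 genes and unnamed probes tested, and 2342 (6.59%) had an unadjusted p under 0.05. The 5 genes passed within each slide as well: on slide 1 TOX3 differed by 9.01 and GNG11 by -11.59, and on slide 2 by 9.61 and -11.85. The count was 7 on slide 1, 20 on slide 2 and 125 with the line as a random and the slide as a fixed block. Quantile normalization of the processed signal and the percentile over probes detected on all arrays each gave 7, of which 71.4% were higher. The count was 159 without BT474, 75 without T47D, 10 without BT474 replicate 1, 14 without MCF-7 replicate 1, 9 with no filter on dim probes and 1, RAB34, with only probes well above background on all arrays; TOX3 did not pass without BT-549 replicate 1 (9.14), nor GNG11 after normexp and quantile normalization together (-6.47). Without MCF-7 it was 39, with TOX3 (9.09) and GNG11 (-11.71) not among them; without MB-468 GNG11 alone passed (TOX3 9.11, KLK11 8.98, PLA2G2A 8.17, RAB34 -7.75), without BT-549 TOX3 alone (KLK11 8.79, PLA2G2A 8.38, GNG11 -11.41, RAB34 -7.46), and by limma 0 genes without MB-231 (1565 at an unadjusted p under 0.05; TOX3 9.17, KLK11 8.56, PLA2G2A 8.20, GNG11 -11.75, RAB34 -7.34) or without MCF-7 and MB-468, chosen after seeing the data (2062; 8.89, 8.96, 8.40, -12.23 and -7.86).

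Which genes are higher or lower in both sensitive lines than in every resistant line was asked of the 12 arrays. Besides KLK11, TOX3 and PLA2G2A, the genes with the widest gaps on the sensitive side included CNNM1, a membrane protein of the cyclin M family, NRXN3, a neurexin of cell adhesion, and CEACAM7, an adhesion molecule of epithelial cells. The nearest sensitive and resistant lines lay 6.42 apart for NRXN3 and 5.26 for CEACAM7, detected on 6 and 5 of 8 resistant arrays. CNNM1 and LINC01087, a long noncoding RNA, were well above background on 1 of 8 resistant arrays, and PIP5K1B, a lipid kinase, on none (at least 29.3-fold higher in the sensitive lines). Probes for UGT1A8 and UGT1A6, glucuronosyltransferases, were at least 57.8-fold and 83.8-fold higher in the mean of the sensitive lines and detected on no resistant array, but the genes of that cluster share most of their sequence, so the member is uncertain, as it is for CEACAM7. These folds rest largely on MCF-7 and are smaller for BT474. UGT1A8 was 2.93 in MCF-7 and -1.94 in BT474, and UGT1A6 3.22 and -1.16. On the resistant side, besides GNG11, RAB34 had a gap of 6.85. MYL9, a myosin light chain of contractile cells, was 5.29 in the resistant against -4.11 in the sensitive lines, and FKBP10, a collagen prolyl isomerase, 3.68 against -3.47; each was detected on 3 of 4 sensitive arrays. GSDME, the gasdermin that forms pores in dying cells, was at least 29.2-fold lower in the sensitive lines (adjusted p = 2.89e-05). PHYHD1, FBXO17, ZNF655, ZNF883 and NLGN1 were at least 55.4-fold, 51.6-fold, 38.0-fold, 20.2-fold and 16.8-fold lower; these and GSDME were well above background on no sensitive array.

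In all, 167 genes and unnamed probes separated the lines, 77 higher (46.1%) and 90 lower in the sensitive lines, of which 56 and 77 have a gene symbol. Without any test 6036 (16.99%) had all 8 differences of 1 sign, against 13.3% by chance. The p-values of this fit, as of each comparison of single lines, measure only the spread between the 2 samples of a line. The count was 206 with the slide as a block and 76 with only probes well above background on all arrays, and a single slide gives no test; it was 1674 without BT474, 1961 without MCF-7, 833 without T47D, 273 without BT-549, 214 without MB-231, 210 without MB-468 and 2076 without MCF-7 and MB-468 (chosen after seeing the data). Leaving out 1 array lowered it to 107 (BT474 replicate 1), 111 and 109 (MB-468), 89 and 102 (MCF-7), and 79 and 91 (T47D), replicates 1 and 2 in turn; by fitted gap, UGT1A8 (1.33), UGT1A6 (2.24) and ZNF655 (-0.81) did not pass after normexp and quantile normalization, nor UGT1A6 without BT-549 replicate 1 (4.94), T47D replicate 1 (4.76) or either MB-468 array (5.13, 5.06), nor LINC01087 without T47D replicate 1 (3.92), BT474 replicate 2 (4.57) or either MCF-7 array (4.69, 4.46).

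**Figure D2:**
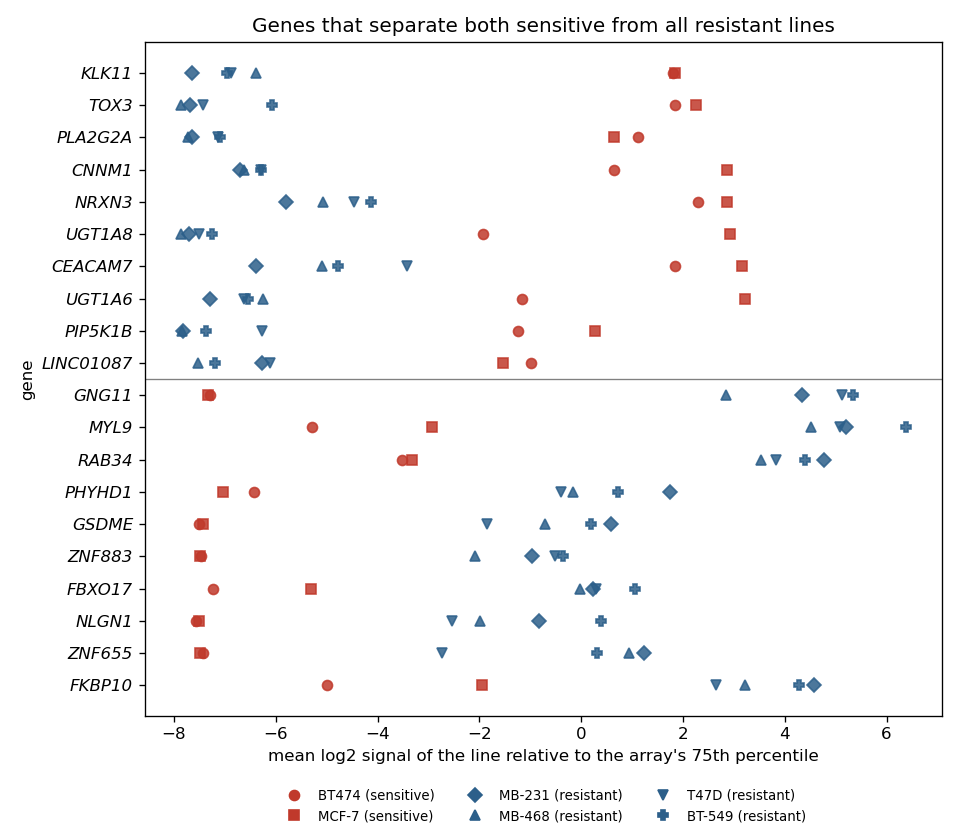
Mean log2 signal of each cell line relative to the array's 75th percentile (horizontal axis) for the 20 named genes with the widest fitted gap between the groups (vertical axis, higher in sensitive lines above the line, lower below); each point is the mean of 2 arrays, red for sensitive and blue for resistant lines. The red and blue points of each gene do not overlap, and on one side many lie at background, as those of GNG11 do in the sensitive lines (-7.31).

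To place these genes in pathways, 22 lists of genes fixed before the data were examined were compared between the response groups with camera. With a preset inter-gene correlation 12 lists passed, 3 higher and 9 lower in the sensitive lines; with an estimated correlation 0 passed, and for each of the 12 the adjusted p = 0.558 with an estimated correlation. No member of a list passed over all genes with the lines as replicates, so members are given by value. These values are differences of group means, and the sensitive lines often lay far apart: BT474 and MCF-7 were 0.50 and 5.18 for HLA-A, -5.95 and 1.97 for PROS1, -6.24 and 3.29 for CCL20, -1.35 and 3.73 for ALDOC, -3.85 and 2.06 for EN1, and -3.65 and 1.90 for PCSK9. A difference is inexact where a line was at background, as for IFI44L and GBP1 (detected on 2 of 4 sensitive arrays), LAPTM5 and ETS1 (2 of 4), RSAD2 and PCSK9 (3 of 8 resistant arrays) and EN1 (2 of 8). Within slide 1 and within slide 2, 11 lists passed. With the line as a random block 13 passed, with or without the slide as a further block; with both blocks the medians of opsonins, MHC class I, interferon-stimulated and luminal genes became -0.71, -0.55, -1.11 and 1.15. The count was 7 after quantile normalization, with or without normexp, and 3 without BT474: epithelial, mesenchymal and proliferation genes.

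Epithelial genes formed the list with the largest shift. All 33 measured members had a higher mean in the sensitive lines, with a median of 2.95 (2.92 on slide 1, 2.98 on slide 2; camera adjusted p = 1.24e-06, and adjusted p = 0.558 with an estimated correlation). EHF, an epithelial transcription factor, RAB25, a GTPase of epithelial traffic, CDH1, E-cadherin, and MARVELD3, a tight junction protein, were higher by fitted values of 5.85, 5.68, 4.74 and 4.65, inexact since each was well above background on only 4 of 8 resistant arrays. The list was not low in all resistant lines: 32 members were lower than in the sensitive lines in BT-549, 27 in MB-231 and 24 in MB-468 (0, 0 and 1 higher), but 1 in T47D, where 7 were higher. CDH1 was 2.82 in T47D and -7.25 in MB-231. No member passed adjusted over the list alone.

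Mesenchymal genes mirrored this. Of 38 measured members 35 had a lower mean in the sensitive lines, with a median of -2.15 (-2.31 and -2.08 within the slides; camera adjusted p = 4.46e-07, and adjusted p = 0.558 with an estimated correlation). VIM, vimentin, and LOXL2, a collagen cross-linking enzyme, differed by -6.75 and -5.11. SPARC, a matrix glycoprotein, and ZEB1, a repressor of epithelial genes, were well above background on 6 of 8 resistant arrays and no sensitive one, at 2.65 and 1.90 in BT-549, 0.43 and 0.47 in MB-231, and -0.73 and 0.06 in MB-468. In BT-549 34 members were higher than in the sensitive lines and 0 lower, in MB-231 and MB-468 21 were higher (6 and 4 lower), and in T47D 7 were higher and 9 lower. VIM reached 6.66 in BT-549, 6.03 in MB-231 and 5.67 in MB-468, and was -2.83 in T47D. It also differed between the sensitive lines, 0.98 in BT474 and -6.72 in MCF-7.

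Luminal and oestrogen-receptor-linked genes were higher in the sensitive lines in 28 of 34 measured members, with a median of 1.05 (1.22 and 0.91 within the slides; camera adjusted p = 0.0035, and adjusted p = 0.558 with an estimated correlation). TFF1, an oestrogen-induced secreted peptide, was higher by 6.52, PGR, the progesterone receptor, by 5.44, FBP1, a gluconeogenic enzyme, by 5.22, and FOXA1, a pioneer factor of luminal cells, by 4.92; the last 3 are inexact, detected on 2, 3 and 6 of 8 resistant arrays. T47D again lay apart from the other resistant lines, with 15 members higher and 4 lower than in the sensitive lines, against 2, 0 and 2 higher and 20, 17 and 21 lower in MB-231, MB-468 and BT-549. PGR was 4.59 in T47D and 3.90 in BT474, but -2.23 in MCF-7. ESR1, the oestrogen receptor, had 3 probes that disagreed in size: the brightest, used here, differed by 0.38, and the others, detected on 6 and 5 of 12 arrays, by 4.58 and 2.59. On that brightest probe ESR1 was 0.27 in T47D, -1.56 in BT474 and -2.51 in MCF-7. The luminal list did not pass without BT474 (median 0.26).

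Genes around ERBB2 were higher in 17 of 19 measured members, median 1.30 (1.34 and 1.27 within the slides; camera adjusted p = 1.40e-04, and adjusted p = 0.558 with an estimated correlation). GRB7 was higher by 3.44. PNMT was 4.44 in BT474 and -3.39 in MCF-7, and IKZF3 was well above background in BT474 alone (2.10), whereas PPP1R1B was 4.10 in MCF-7 and -1.72 in BT474, below T47D (-1.28). ERBB2 itself was 6.02 in BT474 and 2.72 in MCF-7, against 2.20 ± 0.73 (SD, n = 4) in the resistant lines. BT474 exceeded MCF-7 past the threshold in 15 of these 19 genes, and without BT474 the median was 0.09 and the list did not pass.

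Genes of interferon response and antigen presentation had a lower group mean in the sensitive lines. Of 36 measured interferon-stimulated genes 30 had a lower mean, median -1.16 (-1.03 and -1.13 within the slides; camera adjusted p = 4.98e-05, and adjusted p = 0.558 with an estimated correlation). IFI44L, GBP1 and IFI44 differed by -4.04, -3.50 and -3.21, whereas RSAD2, an antiviral enzyme, was higher by 2.998. T47D had the most members higher: 34 of the 36 were higher there than in the sensitive lines and 0 lower (median 3.51), against 24 higher and 3 lower in MB-231, 11 and 5 in MB-468, and 10 and 14 in BT-549. BT474 lay below MCF-7 in 25 of the 36. MHC class I genes were lower in 16 of 20 members, median -0.58 (-0.44 and -0.52 within the slides; camera adjusted p = 0.0110, and adjusted p = 0.558 with an estimated correlation), among them TAP2 (-1.68), HLA-A (-1.46) and PSMB8 (-1.39), while TAPBPL was higher by 2.32. BT474 had the lowest mean level of both lists, but MCF-7 did not lie below all resistant lines. For MHC class I MCF-7 (2.83) exceeded MB-231 (2.65) and MB-468 (2.47) and lay below BT-549 (2.89) and T47D (3.58). For interferon-stimulated genes it (1.49) exceeded MB-468 (0.56) and BT-549 (-0.50) and lay below MB-231 (1.53) and T47D (3.79). Neither list passed without BT474 (medians -0.10 and -0.23) or without T47D (-0.62 and -0.28), and MHC class I did not pass after either quantile normalization (-0.33 with normexp, -0.28 without).

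Pro-phagocytic signals and bridging molecules, the counterpart of the inhibitory ligands, were lower in the sensitive lines in 21 of 24 measured members, median -0.69 (-0.65 and -0.61 within the slides; camera adjusted p = 9.21e-05, and adjusted p = 0.558 with an estimated correlation). VIM, which this list holds as well, PROS1, protein S, MFGE8, a bridge between dying cells and phagocytes, and LRP1 differed by -6.75, -3.16, -2.80 and -2.46. On its other, dimmer probe LRP1 differed by -1.18. MB-231 had 11 members higher and 3 lower than the sensitive lines, BT-549 9 and 0, MB-468 8 and 2, and T47D 5 and 1. Without BT474 the list did not pass (median -0.33).

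NF-kappaB targets were lower in 21 of 23 members, median -0.44 (-0.66 and -0.34 within the slides; camera adjusted p = 0.0054, and adjusted p = 0.558 with an estimated correlation). PLAU, urokinase, and ICAM1, an adhesion receptor, differed by -4.12 and -3.37, IL6 by -1.86, and the chemokine CCL20 by 2.45. The mean level of the NF-kappaB list was low in BT474 alone of the sensitive lines (-1.18). In MCF-7 (1.42) it exceeded MB-231 (0.36), MB-468 (0.47) and T47D (0.49) and lay below BT-549 (1.84). Integrins and adhesion receptors were lower in 20 of 27 members, median -0.51 (-0.48 and -0.47 within the slides; camera adjusted p = 0.0234, and adjusted p = 0.558 with an estimated correlation). MCAM differed by -4.47 and ITGB3, well above background on no sensitive array, was 0.15 in MB-231, -1.33 in MB-468 and -3.10 in BT-549, but ITGB6, an integrin subunit of epithelial cells, was higher, -1.19 in the sensitive lines and well above background on 1 of 8 resistant arrays. T47D had 4 members of the list higher and 7 lower than the sensitive lines (median -0.36), against medians of 0.75 to 0.85 in the other resistant lines. ITGB6 was the member that passed adjusted over the list alone, and it separated all the lines (adjusted p = 0.0078). The NF-kappaB list did not pass without BT474 (-0.18) or after normexp and quantile normalization (-0.22). The integrin list did not pass without BT474 (-0.21), MB-231 (-0.46), MB-468 (-0.34), BT-549 (-0.22) or MCF-7 replicate 2 (-0.46), nor with array medians (-0.71) or quantile normalization (-0.37; -0.23 with normexp).

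Smaller shifts were found in genes of growth, metabolism and stress. Proliferation genes were lower in the sensitive lines in 32 of 39 members, median -0.39 (-0.41 and -0.32 within the slides; camera adjusted p = 1.40e-04, and adjusted p = 0.558 with an estimated correlation), with KIF20A, a mitotic kinesin, at -1.21 and NUSAP1, a spindle protein, at -1.03. In T47D 0 of them were higher and 3 lower than in the sensitive lines (median -0.11), against 10, 5 and 11 higher and 0 lower in MB-231, MB-468 and BT-549. Glycolysis and hypoxia genes were lower in 20 of 30, median -0.26 (-0.36 and -0.28 within the slides; camera adjusted p = 0.0229, and adjusted p = 0.558 with an estimated correlation), with ALDOC at -2.76, SLC2A3 at -1.86 and EGLN3 at 1.58, and with 2 higher and 5 lower in T47D (median -0.28). Immediate early and heat shock genes, which respond to handling, were lower in 15 of 21, median -0.27 (-0.14 and -0.44 within the slides; camera adjusted p = 0.0497, and adjusted p = 0.558 with an estimated correlation). HMOX1 and DUSP1 differed by -1.85 and -1.84 and HSPA1A by 1.73, and 11 of the 21 were higher in BT-549 than in the sensitive lines. The sensitive lines lay at opposite ends for the glycolysis list, whose mean level was highest of all lines in MCF-7 (3.28) and lowest in BT474 (1.82). The proliferation list did not pass after quantile normalization (-0.17) or without MCF-7 and MB-468 (-0.18), nor the glycolysis list after any of 3 other scalings (-0.10 with normexp and quantiles, -0.12 with quantiles alone, -0.46 with array medians), without MB-231 (-0.25), MB-231 replicate 1 (-0.25) or MCF-7 replicate 2 (-0.25) or on slide 2, and its median was 0.0311 without BT474. The stress list did not pass on slide 1, without MB-468 (-0.32), MCF-7 (-0.34), BT-549 (-0.08), BT474 (-0.20) or MCF-7 and MB-468 (-0.28), with array medians (-0.48), probes above background on all arrays (-0.34) or the mean of a gene's probes (-0.27), after normexp and quantile normalization (-0.01) or quantiles alone (0.0146), or without 1 array: replicate 1 of MB-231 (-0.18), T47D (-0.13) or BT-549 (-0.21), or replicate 2 of BT474 (-0.22), MB-231 (-0.17), MB-468 (-0.30) or MCF-7 (-0.18).

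The other lists did not pass. Basal breast cancer genes had a median of -0.14 (camera adjusted p = 0.521), with AXL at -6.03, ETS1 at -4.60 and EN1 at 4.88, while KRT6A was 1.23 in MCF-7 and -6.28 in BT474, within the resistant lines. EGFR, of the same kind, differed by -0.40 and KRT5 by 1.42. Complement regulators had a median of -0.85 (0.105), led by CFH at -3.59, and did pass with the line as a random block, and without MB-231 (-0.69) or T47D (-1.07). Cytokines that act on myeloid cells had a median of -0.43 (0.186), with CSF1, the macrophage growth factor, at -3.69 and CCL2 at -3.17. Apoptosis genes had a median of -0.13 (0.303), and GSDME passed adjusted over the list alone. Genes of sialic acid transfer had a median of -0.26 and a mean of 0.10 (0.372), with ST3GAL1 at 1.94, while ST6GALNAC1 was 1.74 in MCF-7 and -6.90 in BT474, within the resistant lines. Unfolded protein response genes, cholesterol synthesis genes and the markers of macrophages and of fibroblasts and endothelium had medians of -0.14, 0.03, 0.06 and -0.02 (camera adjusted p = 0.167, 0.800, 0.813 and 0.521). HSPA5, a chaperone of the endoplasmic reticulum, differed by -1.14, PCSK9 by 3.67 and LAPTM5 by -4.50, and THY1, detected on no sensitive array, was 5.30 in BT-549. Among these lists myeloid cytokines passed without MCF-7 (-1.10) and without MCF-7 and MB-468 (-1.39), basal genes without MCF-7 (-1.11) or T47D (-0.26), apoptosis genes without MCF-7 (-0.24) and unfolded protein response genes without MCF-7 replicate 1 (-0.21).

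**Figure D3:**
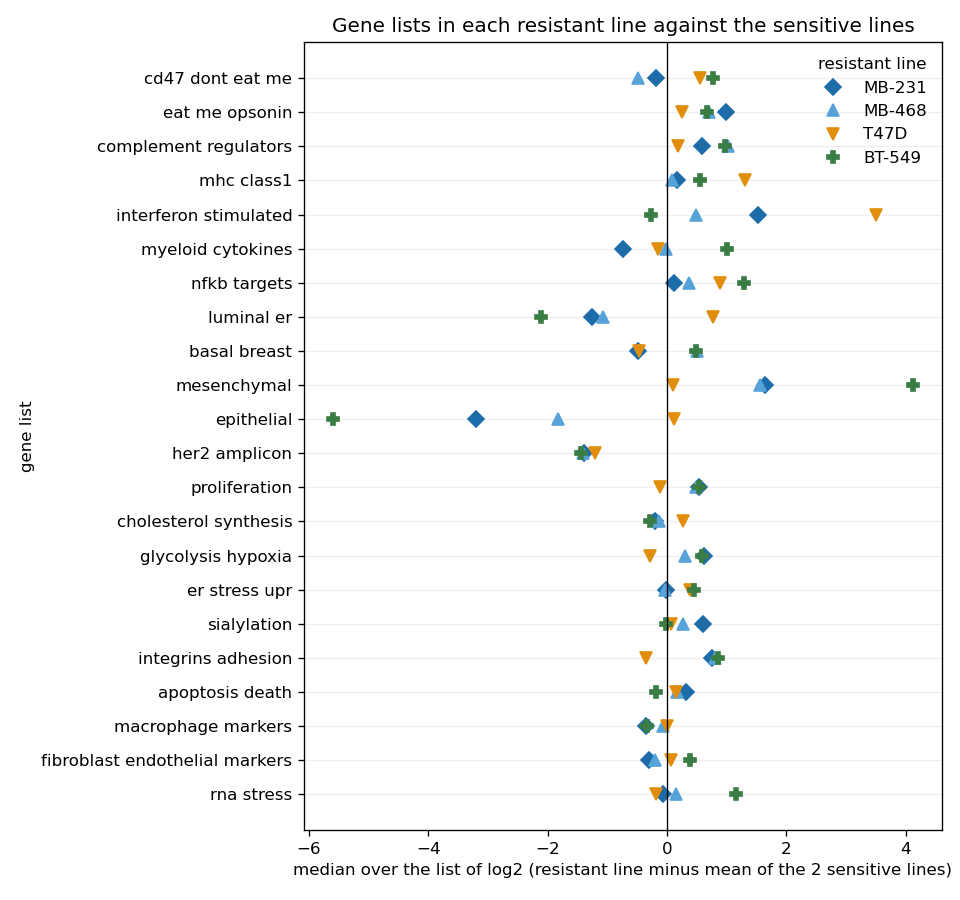
Median over each of 22 gene lists (vertical axis) of the log2 difference between a resistant line and the mean of the 2 sensitive lines (horizontal axis); each symbol is 1 resistant line. T47D lies at 0.12 for epithelial and 0.11 for mesenchymal genes, BT-549 at -5.59 and 4.12, and T47D lies farthest right, at 3.51, for interferon-stimulated genes.

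Each resistant line was also compared with the sensitive lines, since the response classes mix lines of unlike origin. In MB-231, GNG11 was at least 801-fold higher and ANKRD1, a nuclear protein induced by stress, at least 624-fold, while SHISA3 was at least 829-fold higher. RAB25, MUCL1, a mucin-like secreted protein of breast, and MGMT, the DNA repair methyltransferase, were at least 1124-fold, 676-fold and 347-fold lower. ANKRD1 also led in MB-468 (at least 438-fold higher), with MAGEB2, a cancer-testis antigen (10.56 ± 0.45 SE, well above background on 1 of 4 sensitive arrays), and GNG11 (at least 287-fold). MUCL1, CEACAM6 and TOX3 were at least 710-fold, 209-fold and 202-fold lower there. In T47D, GNG11 was at least 1378-fold higher, SERPINA6, the carrier of glucocorticoids, higher by 11.496 ± 0.462 (SE; well above background on 2 of 4 sensitive arrays), and C5orf58 at least 419-fold higher. CST2, a cystatin, and BASP1 were at least 797-fold and 450-fold lower, and CST1, which 1 of 2 arrays of T47D detected, differed by -9.89 ± 0.31 (SE). In BT-549, GNG11 was at least 1607-fold higher and THY1, a surface protein of mesenchymal cells, at least 1569-fold, and MFAP2, a microfibril protein, was higher by 11.10 ± 0.37 (SE; 2 of 4 sensitive arrays). AGR2, EPCAM and RAB25, genes of secretory and epithelial cells, were at least 1653-fold, 1234-fold and 877-fold lower.

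At an adjusted p under 0.05 and a log2 fold of at least 1, 4487 genes and probes were higher and 6746 lower in MB-231 than in the sensitive lines, 3764 and 4376 in MB-468, 4244 and 4897 in T47D, and 4946 and 6356 in BT-549. The 4 comparisons share the sensitive arrays. The totals were 3269 to 5152 after normexp and quantile normalization, 3420 to 5736 with only probes well above background on all arrays, and 3545 to 5160 at a log2 fold of at least 2. They were 11776, 8629, 9584 and 11707 with the slide as a block, and no line has a replicate within a slide.

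Last, the sensitive lines were set against each other, as a measure of how unlike lines of the same response can be. CBLN2, a synaptic organiser, was at least 601-fold higher in BT474 than in MCF-7, MXRA5, a matrix protein, at least 168-fold, SCGB2A2, mammaglobin, at least 154-fold, and NLRP2 at least 457-fold. TCN1, a carrier of vitamin B12, was higher by 9.71 ± 0.74 (SE). In the other direction MUC13, a mucin of intestinal epithelium, and PIGR, the receptor that carries immunoglobulin A across epithelia, were at least 962-fold and 1588-fold lower in BT474, and IGFL2 at least 615-fold. Probes for MAGEA6 and MAGEA12, cancer-testis antigens, were at least 1254-fold and 961-fold lower, with the member uncertain because these genes are nearly identical. BT474 exceeded MCF-7 in 4768 genes and probes and lay below it in 4769, in all 9537. Over the 15 pairs of lines such totals ran from 3223 for MB-231 and MB-468 to 12103 for BT474 and BT-549, and differences between totals were not tested. The arrays labelled MCF-7 also carried genes of intestinal type, such as LGALS4 at 5.77. The total was 10209 with the slide as a block, 4829 after normexp and quantile normalization, 4905 with only probes well above background on all arrays and 4808 at a log2 fold of at least 2.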

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

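The tests of the shared response class, of a fault of 1 array, of the epithelial state, of the scaling and of the splits of the lines for single genes were chosen only after the results were seen; the other tests were written before.

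Arrays labelled MCF-7 carried genes of intestinal type, such as VIL1, villin, at 3.96 against -6.28 or lower in the other lines, and CFTR, GPA33, TSPAN8 and CEACAM5 at 3.13, 1.65, 4.30 and 5.14, together with low ESR1 (-2.51), PGR (-2.23) and GATA3 (-1.58), which were 0.27, 4.59 and 2.77 in T47D (genes other than ESR1 and PGR chosen after their values were seen). On a list of 20 intestinal markers written before this test, of which 17 were tested, all 17 were well above background in MCF-7, 15 were higher there than in every other line, and 14 were also well above background in another line. LGALS4 was 8.54 and PHGR1 7.42 above the next line, and the median excess over the highest other line was 1.61 (quartiles 1.12 and 2.78). That is below the bound of 2 set in advance, and by the rule as written it counts against cells of an intestinal type. The bound lay within the spread of the markers, an allowance that the written rule did not hold. With that allowance, cells of an intestinal type, through a mixed or mislabelled sample, may be present and are not settled by it. A fault of a single array is argued against, since the smaller of the 2 arrays' medians was 1.45; the bounds of that test were reset after this value was seen. No biological explanation was tested.

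MB-468 and MB-231 correlated across genes at 0.958, the next pair, MB-468 and MCF-7, at 0.901 (genes are not independent replicates). Their shared response class is argued against as the whole reason, since the other pairs of resistant lines reached 0.894 at most, and so is a plain exchange of cells, since 1.87% of genes and probes (665) differed by a log2 of at least 3 past the threshold. RNA of MB-231 mixed into the MB-468 samples may explain it: of 34 genes and probes far above the other 4 lines in MB-231, 33 were well above background in MB-468, at a median offset of -1.30 (quartiles -1.56 and -0.95), and 5.88% (2) lay more than 2 below that offset, under the bound of 10% set in advance. Sex-linked markers were left out of that count after its first value was seen, and the next highest share detected among 30 ordered pairs, MB-468 genes in MB-231, was 76.2%. MB-468 genes in MCF-7 followed at 73.3% (11 of 15), whereas MCF-7 genes in MB-468 reached 43.5% (40 of 92). Mixing of the MB-468 samples with cells other than MB-231 was not tested. A likeness of the lines in expression was not tested and stays open.

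Epithelial and mesenchymal genes differed between the response groups through 3 of the 4 resistant lines. Of these, MB-231 and MB-468 are the pair of lines most alike, so they may not count as separate lines. The larger of the absolute medians of T47D on the lists was 0.12, against 1.56 or more in MB-231, MB-468 and BT-549. These medians define the epithelial state by the lists in question, so they cannot decide whether the lists follow that state or the response, which stays open among 4 resistant lines. Under all 10 combinations of 2 lists and 5 scalings the direction and the call were kept, though for both lists camera adjusted p = 0.558 with an estimated correlation between genes. For 3 scalings this was nearly fixed in advance. The deposited table holds the same signal with the same centring. Array medians and the percentile over detected probes shift each array by a constant, and moved the median of all genes by -0.20 and 0.10. Both quantile normalizations could change more and kept the lists, so neither of these removes them. Other scalings were not tested. The test first used a bound of 1 on the smallest absolute median, 0.9988 for mesenchymal genes under normexp and quantile normalization, and was changed after that value was seen.

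Chance was tested by the 15 splits of the 6 lines into 2 and 4, too few for a share under 0.05. With lines as replicates the response groups gave 5 genes and the highest other split 122 (BT474 and T47D against the rest), 5 splits giving at least as many. Separating genes numbered 167 against 585 in that same split and 343 for MB-231 and MB-468, 3 splits giving at least as many, and lists 12 against 13 for MB-468 and BT-549, 4 splits giving at least as many. Splits that call several times the real count point to a structure of the samples, BT474 with T47D and MB-231 with MB-468. Every split keeps both arrays of a line together, so all divide the slides equally.

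Among the 4 resistant lines, 6 of 36 genes and lists tested had 1 line far from the others by Dixon's ratio. Chance gives about 1 in 20 only for independent lines and items. MB-231 and MB-468 are alike, and VIM was tested alone and within lists, so an excess over chance cannot be read from this count. BT-549 stood apart for QPCTL (0.852), for NF-kappaB targets (0.908), for macrophage markers (0.933) and for fibroblast and endothelial markers (0.973). T47D stood apart for ESR1 (0.937) and VIM (0.896).

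Differences between resistant lines passed limma's test across those lines for 13 of the 14 genes named in every case. The log2 range among them was 9.49 for VIM, 5.26 for SIRPA and 4.35 for CD24. For CDH1, KRT5 and SLAMF7 the fitted ranges of 10.06, 5.25 and 4.60 are inexact, since the lowest line (MB-231, MB-468 and T47D in turn) lay below the signal of any probe well above background. The range was 3.67 for ESR1, 3.43 for LRP1, 3.19 for EGFR, 2.50 for CD47, 1.64 for ERBB2, 1.33 for B2M and 1.33 for QPCTL. For CALR the range was 0.75 (adjusted p = 0.0775).

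Control spots, unused in the comparisons, held 1 bright probe. The control probe E1A_r60_1 had a median signal of 5456 over the arrays (2023 to 7805). The other E1A control probes, pooled into a median for each array, gave 35.7 to 162, and negative controls at most 2.72. Whether this probe is brighter by design of the array was not examined, so the difference may be intended.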

How the results depend on the processing

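The fits without both MCF-7 and MB-468, and of each resistant line against BT474 alone, were chosen only after the results were seen; the other alternatives were planned. Array medians in place of the 75th percentile moved the median of all genes from 0.08 to -0.13, a shift of -0.20. Where no cause is given below, the cause was not tested. Named genes kept their direction and side of the threshold in 2746 of 2819 values under other settings and 1834 of 1844 with 1 array left out, and lists in 399 of 484 and 245 of 264. Many of these values belong to genes far from the threshold, which keep their side easily, so the shares do not measure how firm the calls are. Of the genes that passed between the response groups, 0 passed without MB-231 and 1 without MB-468 or without BT-549. The signal over background limits the folds: with only probes well above background on all arrays fewer genes are tested.

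Sensitive against resistant lines, 5 genes became 9 with no filter on dim probes, 1 with probes well above background on all arrays, 20 on slide 2, 159 without BT474, 0 without MB-231, 1 without MB-468, 75 without T47D, 39 without MCF-7 and 1 without BT-549. With the line as a random block there were 197, with the slide as a block too 125, and with the arrays as independent samples 1370, which counts the arrays of a line as unrelated. Without MCF-7 and MB-468 there were 0 (2062 at an unadjusted p under 0.05), and with 1 array left out 4 to 14. The 167 separating genes became 76 with probes well above background on all arrays, 1674 without BT474, 833 without T47D, 1961 without MCF-7, 273 without BT-549, 214 without MB-231, 210 without MB-468 and 2076 without MCF-7 and MB-468. With 1 array left out they were 79 to 151, and with the slide as a block 206.

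For MB-231, MB-468, T47D and BT-549 against the sensitive lines the counts were 4354, 3269, 3726 and 5152 after normexp and quantile normalization, 5336, 3420, 4477 and 5736 with probes well above background on all arrays, and 4838, 3717, 3545 and 5160 at a log2 fold of at least 2. Against BT474 alone they were 12016, 10227, 9231 and 12103. BT474 against MCF-7 gave 4829, 4905 and 4808 under the first 3 of these. Lists that passed numbered 12, and 7 after normexp and quantile normalization, 7 after quantile normalization of the processed signal, 3 without BT474, 0 with an estimated correlation and 11 without MCF-7 and MB-468, where proliferation and stress genes did not pass and myeloid cytokines did. The CD47 difference was -0.0087 without MB-468 and 0.20 to 0.83 under all other settings but 0.07 without MB-231.

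None of the single genes and lists that turned direction had passed, except the glycolysis list (0.0311 without BT474) and the stress list (0.0146 after quantile normalization). After normexp and quantile normalization the medians of unfolded protein response, apoptosis and macrophage lists became 0.0779, 0.0206 and -0.0575, and after quantile normalization alone 0.0704, 0.0254 and -0.0832. With array medians, cholesterol genes became -0.17 and macrophage markers -0.15. With the percentile over detected probes, fibroblast and endothelial markers became 0.0714; with probes well above background on all arrays they became 0.14 and cholesterol genes -0.0438; with no filter, inhibitory ligands became 0.0045. On slide 2 basal genes became 0.0204 and macrophage markers -0.0079. With the arrays as independent samples cholesterol genes became -0.0096. With 1 array left out, cholesterol genes ranged from -0.0055 to 0.0907, fibroblast and endothelial markers from -0.16 to 0.0695, and HSPA6 from -1.64 to 0.0177.

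Without BT474, ESR1 became -0.10, EGFR 0.49, VTCN1 -0.86, PROS1 0.79, HLA-A 0.88, LIF 0.22, XBP1 -4.59e-04, ST6GALNAC4 1.04, FAS 1.15 and HSPA1A -0.23, and the lists of myeloid cytokines, basal genes, apoptosis and fibroblast and endothelial markers 0.90, 0.49, 0.14 and 0.0729. Without MB-231, EGFR became 0.0134 and cholesterol genes -0.0221. Without MB-468, SIRPA became 0.74, basal genes 0.0632 and sialylation 0.17. Without T47D, SIRPA became 0.23 and apoptosis 0.0256. Without MCF-7, KRT5 became -0.75, CCL20 -2.31 and RIPK3 -1.31. Without BT-549, PDCD1LG2 became 0.26, LCP1 -0.0165, inhibitory ligands 0.0234, myeloid cytokines 0.18 and fibroblast and endothelial markers 0.16. Without MCF-7 and MB-468, SIRPA became 0.66, KRT5 -1.35, RSAD2 -0.61, CCL20 -2.77, RIPK3 -1.87 and macrophage markers -0.0186.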

Other observations

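No test in this part was planned: the gene families were chosen after their first members had been seen, and the markers after their values were seen.

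HLA class II genes, which present antigen to helper T cells, were high in T47D. Of 15 measured genes of the family 12 were higher in T47D than in the sensitive lines and 0 lower, and the family's median level there was 2.94, against -1.05 in BT474, -1.67 in MCF-7, -1.71 in MB-468, -2.83 in BT-549 and -3.60 in MB-231. CD74, the invariant chain, was higher by 4.73, HLA-DPA1 by 4.24 and HLA-DPB1 by 5.33, while CIITA, their transcriptional activator, differed by 0.02 and did not pass. BT474 exceeded MCF-7 in 9 of the 15, among them HLA-DQB1 by 1.51. Probes of HLA genes with near-identical sequence leave the exact member uncertain.

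MAGEA genes, cancer-testis antigens, were low in BT474, where their median was -6.94 and 3 of 9 measured genes were well above background. Medians were 2.26 in MB-231, 1.49 in MB-468, 1.96 in T47D, 1.56 in MCF-7 and -3.76 in BT-549. Of the 9, 5 passed as lower in BT474 than in MCF-7, MAGEA4 by a log2 difference of -7.86, and 0 as higher. Among 10 measured CEACAM genes, 3 separated the lines, all higher in the sensitive ones: CEACAM5, CEACAM6 and CEACAM7. Of 16 kallikrein genes only KLK11 separated the lines, whereas 8 were lower in BT474 than in MCF-7, KLK6, KLK7 and KLK8 among them, and 2 higher, KLK5 by 1.30 and KLK12 by 2.63. In both families sequence shared between members leaves single assignments uncertain.

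Keratins of simple epithelia were high in all lines, KRT8 between 6.39 and 7.13 and KRT18 between 6.36 and 6.90. KRT19 was 5.04 to 7.37 in 5 lines and -1.13 in BT-549. GATA3, a luminal transcription factor, was 2.77 in T47D, 1.26 in BT474 and -1.58 in MCF-7. NKX2-1, a transcription factor of lung and thyroid, was 2.36 in MB-231 and 0.78 in MB-468, and -6.93 or lower in the other lines.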
